A study of Bacillus subtilis PY79 with 4 samples.

How the data were processed

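RNA was sequenced from 4 strains of Bacillus subtilis in the PY79 background, with 1 library per strain. The strains were the wild type, a strain overexpressing mraZ, a strain labelled as an mraZ deletion, and a strain overexpressing mraZ with the substitution R15A. Per the labels, cultures grew in LB broth overnight at 22 °C, were brought to mid-log phase (OD600 of 0.5 to 0.8) and set to an OD600 of 0.1. Growth then went on for 2 h at 37 °C, with 1 mM IPTG for both overexpression strains, and 1.3 µg of total RNA went into each library.

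The submitters' processing notes name bcl2fastq, HISAT2, Subread featureCounts and edgeR, without versions or settings. The genome build and gene coordinates are not given in the sources used here, so genes are identified by symbol and locus tag. The deposited count table holds raw read counts for 4052 genes, and each library's sum equals the coding reads of the authors' alignment summary, itself in counts of reads. The authors' tables for the 3 comparisons with wild type hold 3978 genes each. Their signal columns are normalised counts (CPM), each raw count divided by 1 factor per library as tested on the deposited values. The authors' fold columns are on the log2 scale, and their p-value and FDR columns come from an edgeR exact test. All 3978 deposited p-values of each comparison were matched to within 1e-10 by an exact test with the dispersion set to 0.1.

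Raw counts were scaled here with edgeR 4.0.16 (TMM over the 4 libraries) in R 4.3.3, and all other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Of the 4052 genes, 4039 had at least 10 reads summed over the 4 libraries and were kept. Gene-table depth was 8021679 reads for wild type, 20032963 for mraZ overexpression, 12353010 for the library labelled mraZ deletion and 8205194 for mraZ-R15A. Each gene's ratio was given as a log2 ratio with the exact Clopper-Pearson 95% interval of the conditional binomial. That interval and the limit of 3 reads for a gene at 0 cover counting error only, since the reads carry no molecular identifiers and no strain has a replicate. A gene was called higher or lower when its ratio was at least 2-fold and its interval excluded a ratio of 1. A gene with 0 reads in the other library counted as beyond any fold, so its ratio as printed, against 3 reads, is a bound that can lie nearer to 0 than the rule asks. This is a rule of size, not a test between strains, and no p-value was computed for it.

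The comparisons were each altered strain against wild type, and mraZ overexpression against mraZ-R15A overexpression. Genes were named by a rule: among genes with at least 50 reads in 1 of the 2 libraries, the 10 highest and the 10 lowest by the interval bound nearest to 0. The rule also took the genes of the mraZ operon and of the rest of the division and cell wall cluster, amyE, and up to 2 of the highest and 2 of the lowest members of each gene list described. The 33 gene lists cover the operon, the cluster, division, the cell wall, cell states (motility, matrix, competence, sporulation), stress responses, ribosomal proteins, biosynthesis, respiration, carbon and iron use, secreted products and stable RNAs. Each list's median log2 ratio was placed among 10000 random lists of the same size matched on expression in 10 bins, and also among runs of neighbouring genes. The rules, lists and alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0 median-of-ratios scaling, total-count scaling, ribosomal and transfer RNA reads added to the totals, other minimum counts, a 4-fold rule, a rule asking the whole interval to lie beyond 2-fold, and assumed coefficients of variation of 0.1, 0.2 and 0.4 in an exact test.

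A trend along gene order was seen in the mraZ overexpression library, and alternatives for it were chosen after seeing the data. The 3850 genes of the first locus-tag series were kept in file order, from dnaA, and a circular running median over 200 genes was subtracted from each log2 ratio. The other alternatives chosen after seeing the data were the R15A library in place of the wild type, scaling without the mraZ overexpression library, the exact test with a dispersion of 0.1, and 303 groups of genes sharing the first 3 letters of a symbol. Relations between comparisons were computed across 3908 genes with at least 50 reads, beside 50 simulated data sets with no difference between strains, with counting error alone and with an added coefficient of variation of 0.110 taken from the genes themselves.

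The rule of size was tested on simulated data in which 50 genes at a time were altered. With counting error alone, genes altered 4-fold were called in 98% to 100% of cases, and 5 to 11 of 4039 genes were called falsely. With an assumed coefficient of variation of 0.15 between libraries, 27 to 38 genes were called falsely and the intervals held the true ratio for 45.9% to 49.9% of genes. Of 200 unaltered simulated lists, 6.5% fell outside the central 95% of random lists. All 4 libraries and all count columns were used.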

Results

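RNA sequencing measured the transcripts of 4 Bacillus subtilis PY79 strains that differ in mraZ, the first gene of the division and cell wall cluster, which encodes a conserved DNA-binding protein. The strains were the wild type, a strain overexpressing mraZ, a strain labelled as an mraZ deletion, and a strain overexpressing mraZ-R15A, a variant with a substitution in the DNA-binding motif. There was 1 library per strain, so no value below could be set against the spread between replicates. The libraries held 30023772 reads for wild type, 21972828 for mraZ overexpression, 26974688 for the library labelled mraZ deletion and 29639010 for mraZ-R15A. Of the mapped reads, 26.7% fell in coding genes for wild type, 27.8% for mraZ-R15A, 45.9% for the library labelled mraZ deletion and 93.5% for mraZ overexpression. Ribosomal RNA took 0.766%, 0.783%, 0.636% and 0.0521% of them in the same order. Mapped reads outside coding, ribosomal RNA and transfer RNA genes were 72.4%, 71.3%, 53.4% and 6.28%, and what they are was not tested. The widest exact Clopper-Pearson 95% interval of these shares reached 0.0188 percentage points to either side. The 10 genes with most reads took 11.2% of wild-type gene reads and 12.9% of those with mraZ overexpression.

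**Figure D1:**
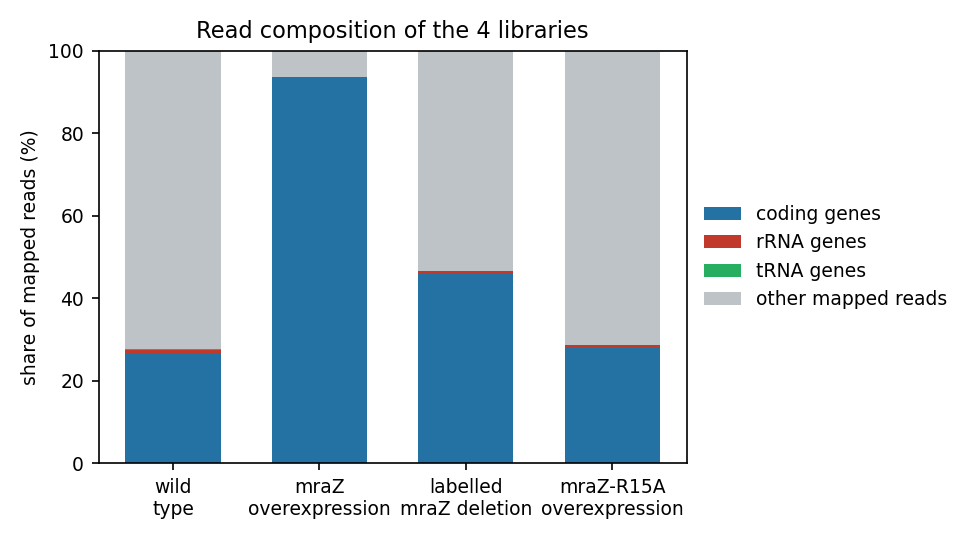
Stacked bars give the share of mapped reads (%) in coding genes, ribosomal RNA, transfer RNA and everything else, with 1 bar per library. Coding genes took 93.5% of mapped reads with mraZ overexpression and 26.7% in wild type.

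The first comparison asks which transcripts differ when mraZ is overexpressed. The mraZ transcript (U712_RS07865) was 39.0-fold higher than in wild type, at a log2 ratio of 5.29 (5.24 to 5.33), from 303693 and 3623 reads. The 3 genes that follow mraZ in its operon were lower by the widest margins in the cluster. The log2 ratio was -3.16 (-3.24 to -3.07) for rsmH (U712_RS07870), a 16S rRNA methyltransferase gene also called mraW. It was -3.58 (-3.77 to -3.40) for ftsL (U712_RS07875), a membrane protein of the division machinery, and -2.44 (-2.53 to -2.36) for pbpB (U712_RS07880), a penicillin-binding protein of septum synthesis. Of the 4039 genes measured, 738 were at least 2-fold higher, 614 at least 2-fold lower, and 2687 neither.

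Among the other 13 genes of the division and cell wall cluster, 1 was higher, 3 were lower and 9 neither, with a median of -0.74. The ratio was 1.41 for spoVD, a penicillin-binding protein of sporulation, -1.20 for ftsZ, the tubulin-like protein of the division ring, and -1.06 for spoVE. The ratio of ftsA, which anchors the ring to the membrane, just passed 2-fold lower. The ratio was -0.89 for mraY, -0.86 for murD, -0.75 for murE, -0.74 for ylxW, -0.70 for sbp, -0.57 for murG, -0.36 for murB and 0.01 for divIB. The last gene, ylxX, lay within 2-fold. Genes near the cluster were also lower as a whole: relative to the running median of its neighbours the ratio was -2.27 for rsmH, -2.70 for ftsL, -1.56 for pbpB, -0.28 for ftsZ and -0.08 for ftsA. Of 6 genes upstream of mraZ, none was higher and 3 were lower, among them gerR at -1.22, and their median was -0.79. Relative to neighbours, 1 of the 13 cluster genes was higher and none lower, and of 5 upstream genes 1 was higher and none lower.

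**Figure D2:**
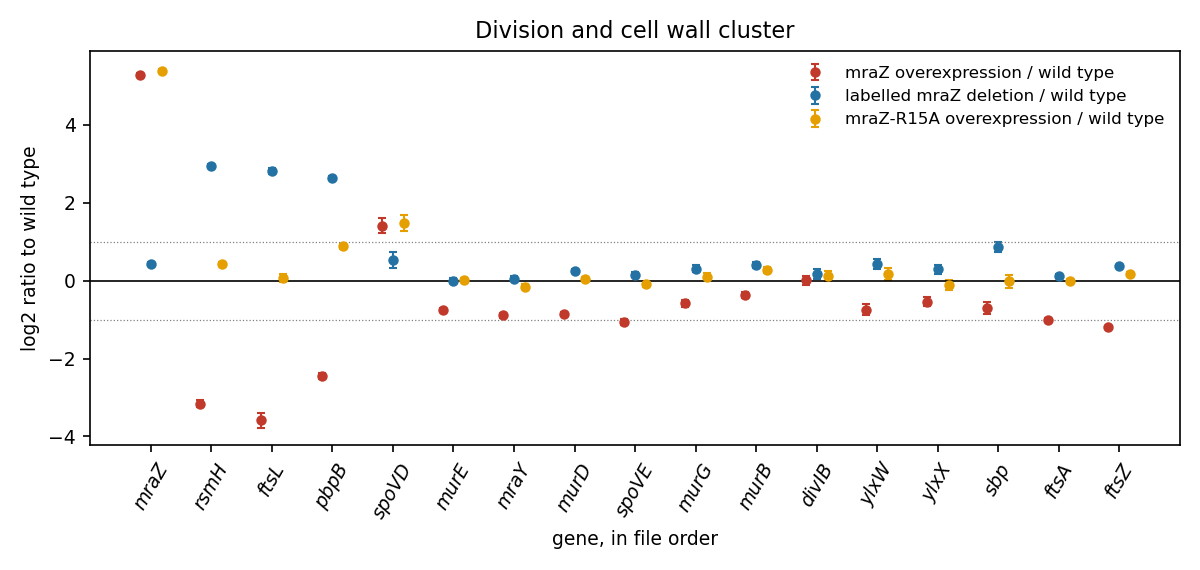
Points give the log2 ratio to wild type of each gene of the division and cell wall cluster in file order, with bars for the 95% counting interval, for the 3 altered strains. The ratios of rsmH, ftsL and pbpB lay between -3.58 and -2.44 with mraZ overexpression and between 2.64 and 2.94 in the library labelled mraZ deletion.

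The remaining genes with the highest ratios included kdgD, a sugar acid dehydratase, at 5.95 (5.33 to 6.64), cotJC, a spore coat protein, at 5.27, and U712_RS21075 at 5.21. They also included yesF at 4.80, amyE, the secreted alpha-amylase, at 4.69, mmgC, an acyl-CoA dehydrogenase, at 4.62, yppD at 4.46, lctP, the lactate permease, at 4.39, and spoIIGA at 4.25. The lowest included tatAC, a twin-arginine translocase subunit, at -3.10 (-3.42 to -2.79), tlpA, a chemoreceptor, at -2.97, yezD at -2.96, yncE at -2.91 and U712_RS09155 at -2.85. The flavodoxin gene fldP stood at -2.74, the regulator gene ntdR at -2.72 and yeeF at -2.67.

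Genes for the use of secondary carbon sources were higher with mraZ overexpression: 36 of 42 were higher and none lower, with a median of 1.88. Examples were rbsC, a ribose transporter subunit, at 3.97 and amyE at 4.69. The amyE ratio was also 4.28 with mraZ-R15A, where 4 of the 42 genes were higher, so it is not particular to the unaltered mraZ. With mraZ overexpression and relative to neighbours, 26 were higher and the median was 1.25. Of 26 genes for growth at low oxygen, 12 were higher and 1 was lower (median 0.99), with lctP at 4.39, the lactate dehydrogenase gene lctE at 3.76, and hmpA at -1.52. Relative to neighbours 7 of them were higher, with a median of 0.28. Of 16 SOS response genes, 8 were higher and none lower (median 0.98), led by dinB at 3.78 and the DNA polymerase gene polYB at 3.59. Relative to neighbours 10 of the SOS genes were higher. The SOS-induced division inhibitor gene yneA was at 2.82 (2.44 to 3.23). In the PBSX prophage, 11 of 32 genes were higher and 1 was lower, with xkdB at 3.42 and the repressor gene xre at -1.46, and relative to neighbours 20 were higher and none lower. Of 33 sporulation genes, 9 were higher and 2 lower (median 0.43), including spoIIGA at 4.25 and spoIIIAD at 3.90, and relative to neighbours 10 were higher and 1 lower.

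Most genes for nucleotide synthesis and motility were lower. Of 15 purine genes, 12 were lower and none higher, with a median of -1.65 and the lowest values at purD (-2.32) and purN (-2.25), while guaB stood at 0.99. Relative to neighbours 13 purine genes were lower, with a median of -1.70. Of 11 pyrimidine genes, 10 were lower and none higher (median -1.55), with pyrB and pyrC both at -2.03, and relative to neighbours 3 were lower, with a median of -0.57. Of 45 flagellar and chemotaxis genes, 33 were lower and none higher (median -1.24), including tlpA at -2.97 and the motor gene motA at -2.16. Relative to neighbours 10 of the flagellar genes were lower, with a median of -0.44. Of 13 autolysin genes, 5 were lower and 2 higher, with lytA at -1.84, lytF at -1.73 and lytH at 1.12, and relative to neighbours 5 were lower and none higher.

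Other lists had members on both sides or few calls. Among 19 other division genes, 3 were higher and 4 lower, with the SOS-induced gene yneA at 2.82 and the nucleoid occlusion gene noc at 1.37. The septal glycosyltransferase gene ftsW was at -1.53 and ylmE at -1.25. Wall elongation genes had 1 of 21 higher and 2 lower, with pbpH at -1.78 and rodZ at -1.05. Teichoic acid genes had 5 of 23 higher and none lower, with tagC, also a member of the SOS list, at 2.84 and dltC at 1.56. Cell envelope stress genes had 5 of 34 higher and 4 lower, with rsiV at 1.91 and floA at -1.36. General stress genes of sigma B had 7 of 25 higher and none lower (median 0.61), with csbC at 2.13, but 2 higher relative to neighbours. Heat shock genes had 1 of 17 higher and 3 lower, with groL at 1.12 and the protease gene htrA at -1.26. Ribosomal protein genes had 6 of 57 higher and 2 lower, with rplA at 1.16 and U712_RS20695 at -2.07, and their median was 0.48 before and -0.19 after the neighbours were taken off. Relative to neighbours, other division genes had 1 higher and none lower, and teichoic acid genes 1 higher and none lower, with a median of -0.17. Wall elongation and heat shock genes each had 1 higher and 1 lower, envelope stress genes 2 higher and 1 lower, and ribosomal protein genes 4 of 53 higher and 1 lower.

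Among biosynthesis lists, arginine had 3 of 9 lower and none higher, with argC at -1.21, and branched-chain amino acids had 1 of 11 higher (ilvE at 1.59) and 1 lower (ilvA at -1.11). Histidine and tryptophan had 3 of 15 higher and none lower, with trpE at 1.90, and methionine and cysteine had 2 of 25 higher and 3 lower, with metN at 1.37 and mtnD at -1.53. Fatty acid genes had 1 of 16 higher (fabZ at 1.63) and 2 lower, including cdsA at -1.39. The tricarboxylic acid cycle had 2 of 12 higher, fumC at 1.88 and citZ at 1.06, and aerobic respiration had 2 of 23 higher and 1 lower, with ctaD at 1.72 and ndh at -1.20. Glycolysis and gluconeogenesis had 4 of 15 higher and 1 lower, with the gluconeogenic genes gapB at 2.61 and pckA at 2.36. Iron uptake had 5 of 18 lower and none higher, with ykuO at -1.73. Biofilm matrix genes had 3 of 20 lower and none higher, with sipW at -1.71 and the fibre protein gene tasA at -1.52. Competence genes had 1 of 20 higher (ssbB at 1.01) and 3 lower (comGG at -1.37). Antimicrobial genes had 3 of 36 higher and 6 lower, with ppsB at -2.13, and secreted enzyme genes had 5 of 19 higher and 4 lower, with bglS at 2.65 and pelB at -1.67. The 3 stable RNAs were neither higher nor lower, with ssrA at 0.02. Relative to neighbours, none of the arginine, branched-chain, fatty acid and competence genes was higher or lower. Histidine and tryptophan and the tricarboxylic acid cycle each had 3 higher, methionine and cysteine and aerobic respiration each had 2 higher, and none of these genes was lower. Iron uptake then had 4 lower, biofilm matrix 1 and antimicrobials 8, with none higher, while glycolysis and gluconeogenesis had 2 on each side and secreted enzymes 3 on each side.

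The ratios with mraZ overexpression followed gene order. The 963 genes at both ends of the order, around dnaA, had a median of 0.91, with 410 higher and 5 lower, and the 963 genes in the middle had a median of -0.68, with 63 higher and 306 lower. The difference was 1.59, and the running median held 31.3% of the variance. The same difference was 0.01 for the library labelled mraZ deletion and -0.032 for mraZ-R15A. Relative to neighbours, 411 of 3850 genes were higher and 275 lower with mraZ overexpression. Under total-count scaling, which shifts each ratio by -0.22, the calls were 534 higher and 853 lower, and the medians of the wall elongation, heat shock, glycolysis, biofilm matrix and stable RNA lists turned negative.

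**Figure D3:**
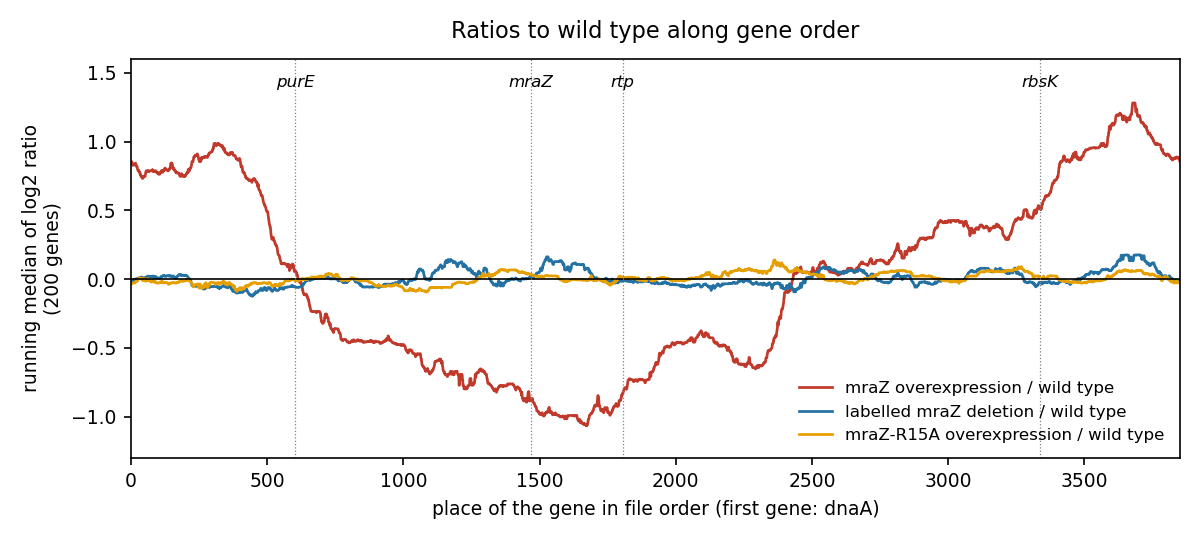
Lines give the running median over 200 genes of the log2 ratio to wild type against the place of the gene in file order, from dnaA, for the 3 altered strains. The mraZ overexpression line is high at both ends (median 0.91) and low in the middle (-0.68), while the other two stay near 0.

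The second comparison asks which transcripts differ in the strain labelled mraZ deletion. The genes downstream of mraZ in its operon were higher than in wild type: rsmH at 2.94 (2.90 to 2.98), ftsL at 2.82 (2.74 to 2.89) and pbpB at 2.64 (2.59 to 2.69), from 61972, 16280 and 35829 reads. The library also held 7007 mraZ reads, at a ratio of 0.43 (0.37 to 0.49), so mraZ was not lower than in wild type, and the part of the gene removed is not given in the sources used here. None of the other 13 cluster genes reached 2-fold, with sbp at 0.86, spoVD at 0.53, ftsZ at 0.37 and ftsA at 0.13, and their median was 0.29. Over all genes, 226 were higher, 104 lower and 3709 neither.

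The highest genes were lctE at 6.77 (6.45 to 7.11), cydA, a cytochrome bd oxidase subunit, at 5.01 (4.30 to 5.82), lctP at 4.60 and U712_RS21385 at 4.60. They also included folEB, a GTP cyclohydrolase, at 3.41, ssuB at 3.39, the gluconokinase gene gntK at 3.02 and the ribose transporter gene rbsA at 2.92. The lowest were yezD at -6.04 (-6.65 to -5.49) and ytlI, a regulator gene, at -4.62 (-5.07 to -4.20). They also included yxeK at -3.86, snaB at -3.72, yjnA at -3.71, yxeM at -3.44, yxeN at -2.88, and the cysteine synthesis genes mccB at -2.63 and mccA at -2.37. The lipoprotein gene yhcN was at -3.73.

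PBSX prophage genes were higher in the library labelled mraZ deletion, with 22 of 32 higher, none lower and a median of 1.17, including xkdM at 1.77 and xkdJ at 1.76. Secondary carbon genes had 23 of 42 higher and none lower (median 1.07), with rbsD and gntK both at 3.02, and low-oxygen genes had 7 of 26 higher and none lower. Ribosomal protein genes had 12 of 57 higher and none lower, with rpsQ at 1.69 and rpmC at 1.67. General stress genes had 6 of 25 higher and none lower, with gsiB at 1.74 and gspA at 1.41, and respiration genes had 3 of 23 higher, with ctaF at 1.20. Methionine and cysteine genes had 6 of 25 lower and none higher. Flagellar genes had 2 of 45 higher, flhF at 1.12 and cheB at 1.03, and sporulation genes had 2 of 33 lower, including spoIID at -1.42. Histidine and tryptophan had 2 of 15 higher (hisG at 1.51 and trpC at 1.11), but 10 of 15 lay below 0, with a median of -0.35. Pyrimidine synthesis had 1 of 11 lower (pyrR at -1.21), and iron uptake had 1 of 18 higher (dhbA at 1.21). Biofilm matrix genes had none past 2-fold, but 19 of 20 lay above 0, with a median of 0.61 and epsL at 0.90.

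In this comparison total-count scaling, which shifts each ratio by -0.10, gave 188 genes higher and 128 lower. With the mraZ-R15A library as the reference in place of wild type, 162 genes were higher and 145 lower.

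**Figure D4:**
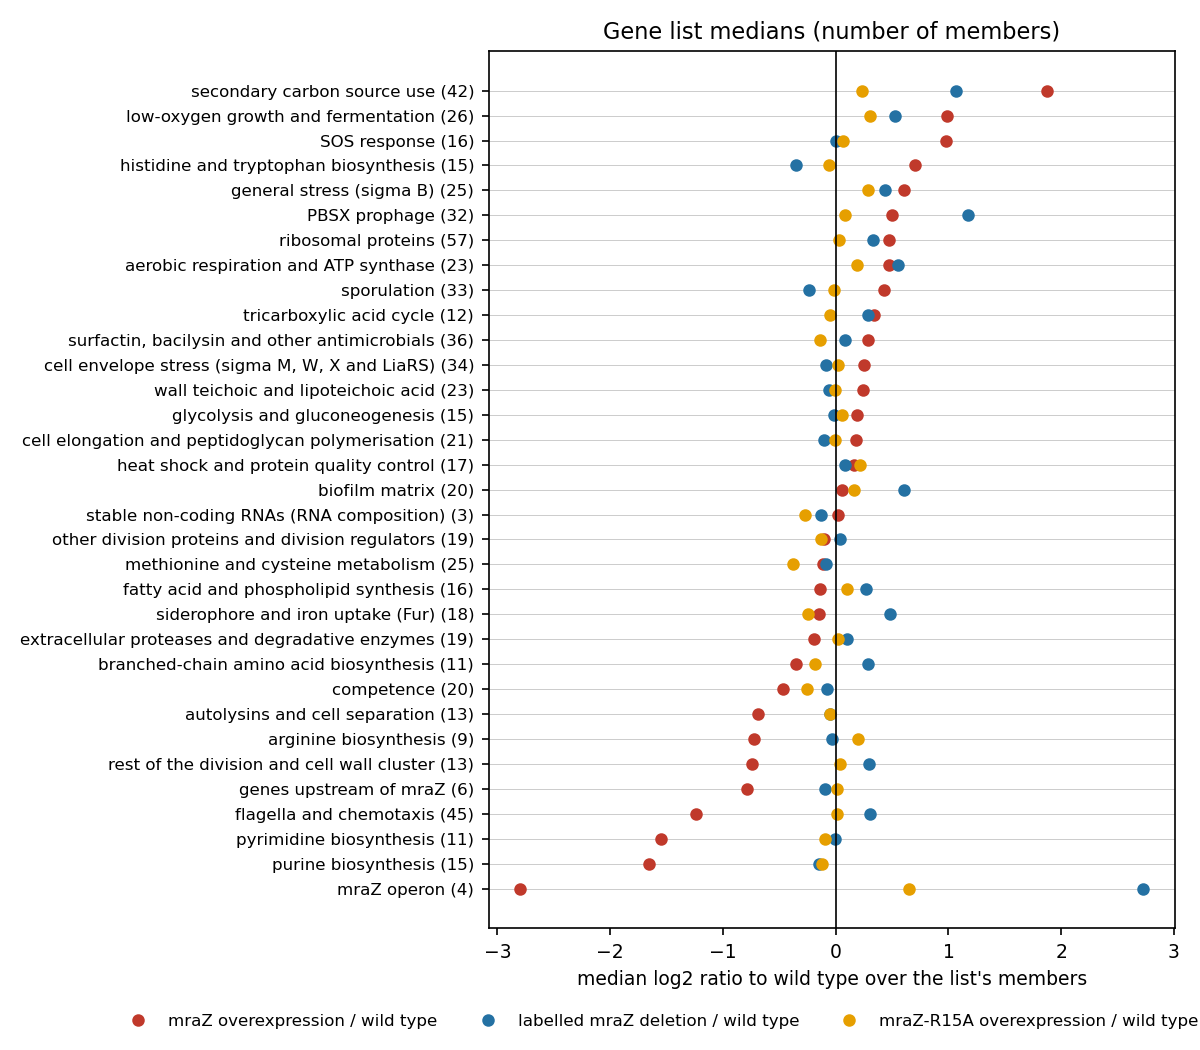
Points give the median log2 ratio to wild type over the members of each gene list, for the 3 altered strains, with the number of members after each name. Secondary carbon use lies at 1.88, 1.07 and 0.23 for mraZ overexpression, the library labelled mraZ deletion and mraZ-R15A, and purine synthesis at -1.65, -0.15 and -0.13.

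The third comparison asks which transcripts differ when the R15A variant is overexpressed. The mraZ transcript was 42.0-fold higher than in wild type, at 5.39 (5.35 to 5.44), but the genes downstream of it were not lower: rsmH was at 0.42 (0.37 to 0.47), ftsL at 0.06 (-0.04 to 0.16) and pbpB at 0.88 (0.82 to 0.93). In the rest of the cluster, spoVD was higher at 1.49 and the other 12 genes were neither, with ftsZ at 0.18 and ftsA at 0.00. Over all genes, 168 were higher, 72 lower and 3799 neither.

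The highest genes were lctE at 6.46 (6.14 to 6.80), kdgD at 5.51 and the glucose uptake gene glcU at 5.34. They also included lctP at 4.90, spoIIGA at 4.58, amyE at 4.28 (4.12 to 4.45), cydA at 4.20, the polyamine acetyltransferase gene bltD at 3.90 and yesF at 3.82. The lowest included the cystine transporter gene tcyP at -4.73 (-4.87 to -4.60), mccB at -4.56, ytlI at -3.95, yxeN at -3.80, mccA at -3.36, snaB at -3.35 and yjnA at -3.24. They also included yezD at -6.48 (-7.36 to -5.73), yhcN at -4.66 and U712_RS04825 at -4.65. Methionine and cysteine genes had 8 of 25 lower and none higher (median -0.38).

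Low-oxygen genes had 5 of 26 higher, sporulation genes 6 of 33 (spoIIIAD at 3.57) and secondary carbon genes 4 of 42 (the mannitol transporter gene mtlA at 3.47), with none lower in each. Secreted enzymes had 3 of 19 higher, including amyE and the protease gene bpr at 1.90, PBSX genes had 3 of 32 higher, and heat shock genes had the ATPase gene clpE higher at 1.46. Flagellar, purine, pyrimidine and competence genes had no member past 2-fold in either direction, with medians of 0.01, -0.13, -0.10 and -0.26.

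The fourth comparison asks what differs between the strain overexpressing mraZ and the strain overexpressing mraZ-R15A, which held similar mraZ levels, at a ratio of -0.11 (-0.12 to -0.10). The downstream genes were lower with the unaltered mraZ: rsmH at -3.57 (-3.66 to -3.49), ftsL at -3.64 (-3.83 to -3.46) and pbpB at -3.32 (-3.40 to -3.24), which are 11.9-fold, 12.5-fold and 10.0-fold. In the rest of the cluster 2 of 13 genes were lower, ftsZ at -1.38 and ftsA at -1.01, and spoVD was at -0.08. Relative to neighbours none of the 13 was higher or lower, with ftsZ at -0.47 and ftsA at -0.10, while rsmH was at -2.69, ftsL at -2.76 and pbpB at -2.44. Over all genes, 698 were higher, 627 lower and 2714 neither.

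The highest genes included yxeN at 4.90, sndB at 4.79, mccB at 4.76, yxeQ at 4.57, the proline dehydrogenase gene putB at 4.02, mmuP at 3.99, a cysteine synthase gene (U712_RS00430) at 3.67 and rocE at 3.65. Also there were yybF at 4.06 and U712_RS18860 at 3.95. Against wild type, mccB stood at 0.20 with mraZ overexpression and -4.56 with mraZ-R15A, and yxeN at 1.10 and -3.80. So low values with mraZ-R15A account for much of some of these ratios, while putB stood at 3.81 and -0.21. After the operon genes, the low end held yoyG at -3.47, ylaI at -3.31, tatAC at -3.13, yncE at -3.04, yjhA at -3.03, U712_RS09155 at -2.95 and tlpA at -2.92.

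Secondary carbon genes had 29 of 42 higher and none lower, with the ribose transporter gene rbsA at 3.74, and SOS genes had 7 of 16 higher and none lower, with dinB at 3.36 and the excision repair gene uvrA at 2.60. Methionine and cysteine genes had 8 of 25 higher and 1 lower (mtnB at -1.43), and PBSX genes had 13 of 32 higher and 3 lower. Against wild type, methionine and cysteine genes had 2 higher and 3 lower with mraZ overexpression, and none higher and 8 lower with mraZ-R15A. Low-oxygen genes had 6 of 26 higher and 3 lower, but none higher and 4 lower relative to neighbours. Purine genes had 11 of 15 lower and 1 higher (purN at -2.17 and guaB at 1.07), pyrimidine genes 9 of 11 lower and none higher (pyrC at -2.13), and flagellar genes 32 of 45 lower and 1 higher (flgD at -2.46 and fliW at 1.34). Relative to neighbours the lower genes numbered 11 for purine, 1 for pyrimidine and 13 for flagella, with none higher. The higher genes then numbered 18 for PBSX (median 1.18), 9 for SOS and 10 for methionine and cysteine, with none lower, and 23 for secondary carbon, with 1 lower. These ratios followed gene order as well, with a difference of 1.61 between the ends and the middle. Total-count scaling gave 490 genes higher and 831 lower.

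The 3 comparisons with wild type share its library, which alone makes their ratios move together. Both overexpression libraries had 126 genes higher in common, where independent calls would give 30.7 and simulations with no difference between strains gave 2.44. The mraZ overexpression library shared 110 higher genes with the library labelled mraZ deletion (41.3 and 2.96), and the latter shared 52 with mraZ-R15A (9.40 and 2.64). For lower genes the shared numbers were 16 (10.9 and 0.82), 32 (15.8 and 1.28) and 36 (1.85 and 1.14). Part of each excess over independent calls may come from the wild-type library, which cannot be split. Data simulated with no difference between strains hold few calls. In the separate simulations of the rule of size, false calls were 27 to 38 per comparison at an assumed coefficient of variation of 0.15, above the 0.110 used here. The simulated shared numbers are therefore small in any case and cannot size that part. In all 3 comparisons 39 genes were higher, counting 1 with 0 reads in wild type, among them lctE, lctP, cydA, amyE, mtlA and gntK, and 9 were lower, among them yezD, tcyP, yjnA and ytlI. Across 3908 genes, which are not independent replicates, Pearson's r (with Spearman's rho) was 0.25 (0.18) between mraZ overexpression and the library labelled mraZ deletion, 0.39 (0.22) between both overexpression libraries, and 0.51 (0.49) for the remaining pair. Their covariances were 0.184, 0.287 and 0.217, beside simulated covariances of 0.0465, 0.0465 and 0.0464. The simulated r of 0.555, 0.537 and 0.521 lay above each r observed. The simulated ratios held counting error and added spread alone, so their r cannot be set against an r that also holds differences between strains. The only pair without a common library, mraZ overexpression against mraZ-R15A and the library labelled mraZ deletion against wild type, had an r of -0.048 (-0.079 to -0.017) and a rho of -0.0066. Without the cluster and the flagellar list that r was -0.030 (-0.061 to 0.0020), and over genes with at least 200 reads it was -0.073 (-0.106 to -0.040). The intervals of r for this pair treat genes as independent, which they are not, so they cannot set r apart from 0. This pair had 71 genes higher in both (39.1 for independent calls and 0.12 simulated), 15 lower in both (16.1 and 0.22), 44 higher in the first and lower in the second (18.0 and 0.12), and 29 the reverse (35.1 and 0.12).

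In the authors' deposited tables, 446 genes were higher and 320 lower by at least 2-fold with a p under 0.05 for mraZ overexpression, and 201 of these passed an FDR of 0.05. The authors' deposited tables gave 150 genes (110 higher, 40 lower) for the strain labelled mraZ deletion, 35 of them by FDR. For mraZ-R15A, the values in the authors' deposited table gave 120 genes (84 higher, 36 lower), 47 of them by FDR. Those p-values rest on an assumed dispersion of 0.1, since the deposited design has 1 library per strain.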

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

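Every test below was chosen only after the result it concerns was seen. For genomic DNA among the reads, what the test would show was written down before the value of that test was seen. Intervals of single genes cover counting error only, and those of a median or of a difference along gene order come from the spread over genes. The genes named here as members of shared or opposite sets were chosen after their values were seen.

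Of all genes, 10 were at least 2-fold higher with mraZ overexpression and at least 2-fold lower with mraZ-R15A, both against wild type, where independent calls would give 13.2. They included a cysteine synthase gene (U712_RS00430), the S-methylmethionine permease gene mmuP, the sulfite reductase gene cysI and the sulfur compound genes sndB, yxeN, yxeO and yxeQ, and the difference was not tested. In sndB the ratios were 1.89 and -2.90, and in yxeQ 2.14 and -2.43. Relative to neighbours 2 of the 10 kept both calls, lplC and yybP, and the others lost the higher one, with 0.68 for sndB, 0.92 for yxeQ, 0.42 for mmuP, -0.14 for yxeN and 0.87 for U712_RS00430. The reverse held for 3 genes, clpE (-1.10 and 1.46), yoyG and U712_RS15175, where independent calls would give 25.5, and that difference was not tested either. Relative to neighbours U712_RS15175 kept both calls, clpE was at -0.32 with mraZ overexpression, and yoyG has no place in the gene order used.

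Between mraZ overexpression and the library labelled mraZ deletion, 17 genes were higher in the former and lower in the latter, including mmuP, yxeM, yxeN, glnT and putM, where independent calls would give 19.0. Relative to neighbours 3 of 16 with a place in the gene order kept both calls, prtG, putM and gerBB. In the other direction 13 genes were lower with mraZ overexpression and higher in the library labelled mraZ deletion, against 34.4 for independent calls. These held rsmH, ftsL and pbpB, the flagellar and chemotaxis genes flhF and cheB, the DNA translocase gene spoIIIE, ssuB, pksJ, dhbA and liaI. Relative to neighbours 6 of 12 kept both calls, rsmH, ftsL, pbpB, ssuB, dhbA and liaI, while flhF was at -0.11, cheB at -0.19, spoIIIE at -0.15 and pksJ at -0.27 with mraZ overexpression. These differences were not tested. All 4 numbers of opposite genes lay below those of independent calls, and simulations with no difference between strains, which hold few calls, gave 0 for each.

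Transfer RNA reads were not part of the gene comparisons. Transfer RNA took 0.163% of mapped reads with mraZ overexpression and 0.0811% in the library labelled mraZ deletion, against 0.0611% in wild type and 0.0581% with mraZ-R15A. Set against coding reads the order turned, with transfer RNA at 0.174% and 0.177% of their number, against 0.228% in wild type and 0.209% with mraZ-R15A.

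The library labelled mraZ deletion held 7007 mraZ reads, a log2 ratio of 0.43 to wild type. Wild-type cells under that label are argued against by the operon, where the least raised of rsmH, ftsL and pbpB was at 2.64 (2.59 to 2.69), beyond the 2-fold that such cells would allow. Reads leaking from the overexpression libraries would have to reach 1.53% of those libraries' mraZ reads, and over 45 other genes high in both the median excess was 1.17% (-0.25% to 7.69%), an interval too wide to decide, though 6 of the 45 lay below 1.53% with all their reads counted, among them kdgD at 1.09% (0.783% to 1.49%). Wild type held 3623 mraZ reads in all, fewer than 7007, which argues against a leak that put as many mraZ reads into wild type. A leak mainly into the library labelled mraZ deletion was not excluded. A part of mraZ left in place and read from the operon's own promoter may also account for the reads. But mraZ reads per rsmH read relative to wild type, at 0.175 (0.167 to 0.184), would be as low if reads leaked beside the higher rsmH. So such a leak and a kept part cannot be told apart by these values. How much of the gene was removed is not given in the sources used here.

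With mraZ overexpression, genes at the ends of the gene order, around dnaA, were higher than genes in its middle by 1.59 in log2 ratio. An odd wild-type library is argued against, since the difference was 1.61 against the mraZ-R15A library, and an effect of IPTG or of protein load shared with mraZ-R15A is argued against by -0.032 in that strain. Genomic DNA among the reads would shrink the difference in genes with many reads, but it was 1.45 (1.35 to 1.59) in the genes with most reads, the top of 4 groups by read number, and lay between 1.25 and 1.77 in those with fewest. A higher copy number of genes near the replication origin may be a biological explanation, but no DNA was measured and it was not tested. GC content was not tested for want of a sequence in the sources used here, and the read composition of this library, with 93.5% of mapped reads in coding genes, differs along with its strain.

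Apart from mraZ, 45 genes were at least 4-fold higher in both overexpression libraries than in wild type, counting 2 with 0 wild-type reads that do not reach 4-fold in both against a floor of 3 reads, and among them were kdgD, amyE, lctP, spoIIGA, glnT and mmgC. If the wild-type library were low for these genes, the third library would lie above it too, and its median there was 0.43 (-0.13 to 1.41), with 17 genes higher and 2 lower, an interval that holds both no difference and a 2-fold one. IPTG or a construct common to both strains may also raise them, and 66.7% of the 45 genes lay within 2-fold between the overexpression libraries. That share would be as likely if either form of MraZ raised them, so inducer, construct and protein cannot be told apart, each being present in both strains.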

How the results depend on the processing

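The alternatives relative to neighbouring genes, with another reference library, without the mraZ overexpression library and with a dispersion of 0.1, and their tests, were chosen only after the results were seen. No paired analysis was possible because each strain has 1 library and the labels pair none, and with 1 library per strain leave-one-out cannot be done. Of the numbers of genes called, 55 stayed within 1.5 times the reported number and 19 did not, and no number under median-of-ratios scaling, total-count scaling, no minimum count or rRNA and tRNA reads in the totals was among the 19. With rRNA and tRNA reads in the totals, log2 ratios shifted by 5.7e-06 at most, so that setting could not move the numbers. Asking for 4-fold gave 181 higher and 90 lower for mraZ overexpression, 55 and 27 for the library labelled mraZ deletion, 56 and 31 for mraZ-R15A, and 123 and 90 for mraZ overexpression against mraZ-R15A, fewer by construction. So did a whole interval beyond 2-fold, with 117 and 41 for the library labelled mraZ deletion, 74 and 35 for mraZ-R15A, and 451 higher for mraZ overexpression against mraZ-R15A. At least 50 reads in 1 of the 2 libraries left 105 and 44 for mraZ-R15A, with fewer genes measured. Relative to neighbours the numbers were 411 and 275 for mraZ overexpression and 374 and 326 against mraZ-R15A. There the median of the rest of the division and cell wall cluster turned from -0.74 to 0.16 against wild type and to 0.14 against mraZ-R15A, and that of envelope stress against mraZ-R15A to -0.085, since the trend of their neighbours was removed. The numbers of genes called in opposite directions, 10, 3, 17 and 13, were 2, 2, 5 and 7 there. Of the list medians under all alternatives, 545 lay within the spread of the reported median and 42 outside it, and the other 3 are those just named. Beyond these 3, 56 medians also changed sign, all in lists inside the central 95% of random lists. Of 132 list percentiles, many lay inside the central 95% of random lists to begin with, so 132 is not the number that could be lost. Placed among runs of neighbouring genes, 24 that lay outside it no longer did, and the cause was not tested. For mraZ overexpression against wild type these were SOS (at 88.3), low oxygen (89.9), sigma B (75.4), the rest of the cluster (17.8) and autolysins (20.6), and against mraZ-R15A they were SOS, the rest of the cluster, envelope stress and arginine. For the library labelled mraZ deletion they were the rest of the cluster, flagella, sigma B, branched-chain amino acids, the tricarboxylic acid cycle, iron uptake and fatty acids. For mraZ-R15A they were the mraZ operon (96.5), other division genes, biofilm matrix, heat shock, branched-chain amino acids, respiration, antimicrobials and stable RNAs. Of the numbers of genes at p under 0.05 and 2-fold, 4 stayed within 1.5 times those of the authors' deposited tables and 8 did not. Of those 4, 3 came from the exact test with a dispersion of 0.1, which already matched the deposited p-values and so could not move. A dispersion is the square of a coefficient of variation. The dispersion of 0.1 behind the authors' deposited tables thus lies between coefficients of variation of 0.2 and 0.4. With assumed coefficients of variation of 0.1, 0.2 and 0.4 in its place, the numbers of genes were 1345, 1316 and 410 for mraZ overexpression. They were 323, 292 and 97 for the library labelled mraZ deletion, and 235, 193 and 89 for mraZ-R15A, since a larger assumed spread calls fewer genes. Counting all genes with an FDR under 0.05, without the 2-fold rule, the first comparison gave 2451, 1170 and 53. Pearson's r between mraZ overexpression and the library labelled mraZ deletion was 0.21 at 200 reads or more. Depth limits genes with few reads: of 4039 genes, 7 had 0 reads in 1 library of the mraZ overexpression comparison and 13 in that of mraZ-R15A.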

Other observations

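The tests of gene groups sharing the first letters of a symbol, and the groups named here, were chosen only after their values were seen, among 303 such groups. With mraZ overexpression, all 6 hut genes for histidine use were higher than in wild type (median 2.24, or 0.95 relative to neighbours), as were 6 of 7 roc genes for arginine and ornithine use (median 2.37, or 1.42 relative to neighbours) and 3 of 4 put genes, among them the proline dehydrogenase gene putB (median 2.76, or 1.91 relative to neighbours). The roc genes had none past 2-fold in the library labelled mraZ deletion or with mraZ-R15A, with medians of -0.03 and -0.21. All 7 mdx genes for maltodextrin use were higher (median 2.30, or 1.98 relative to neighbours), and 4 of 5 mmg genes, known from mother-cell metabolism, were higher, with a median of 3.94, or 4.43 relative to neighbours. The mmg genes were higher with mraZ-R15A too, with 4 of 5 and a median of 2.57, and none was called higher or lower in the library labelled mraZ deletion. All 4 app genes for peptide uptake were lower with mraZ overexpression (median -2.16, or -1.49 relative to neighbours), as were all 5 dpp genes for dipeptide uptake (median -1.37, or -0.62 relative to neighbours).

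Of 9 tcy genes, 5 were lower in the library labelled mraZ deletion (median -1.54) and 5 with mraZ-R15A, while with mraZ overexpression 3 were higher and 2 lower. Of 8 yxe genes, 5 were lower in the library labelled mraZ deletion (median -2.38), 4 with mraZ-R15A (median -1.08), and 5 were higher with mraZ overexpression (median 1.19, or -0.04 relative to neighbours). The 4 cyd genes of the cytochrome bd oxidase were all higher with mraZ overexpression (median 3.01), and 3 of 4 were higher in each of the other two strains, with medians of 2.51 and 2.52. Relative to neighbours the order of the cyd medians turned, to 1.81 with mraZ overexpression, 2.40 in the library labelled mraZ deletion and 2.46 with mraZ-R15A.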
